A study of Homo sapiens with 25 samples.

How the data were processed

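The data are 24 ChIP-seq peak lists of MCF-7 cells, from 4 antibodies (pan-ER and pS118 from 3 suppliers), 2 treatments and 3 replicates each. Per the labels' protocols, cells were stripped of hormones for 3 days and treated for 30 min with 10 nM E2 or 0.01% ethanol. Libraries were amplified for 4 and then 14 PCR cycles around a size selection of 400 to 500 bp and sequenced as 50 bp reads. Samples were grouped by the antibody and treatment given in the labels, with replicate numbers from the sample titles. A further vehicle sample, the input, has no list and was not analysed here.

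Per the submitters' processing notes, Bowtie and HOMER were used with genome build hg19; their versions, settings and the peak threshold are not given in the sources used here. Peaks were listed per library, not on pooled replicates. Per the file headers, each peak has a chromosome, start, end, identifier, strand and a normalized tag count, a signal value that the authors scaled within each library. In the lower values of every list, 100% were whole multiples of a fixed step to within 0.01, so that a step was taken as 1 tag. A tag was worth 0.172 to 0.397 normalized tags and the lowest peak of a list held 11 to 20 tags, so a peak near the threshold rests on few tags. The scaling total is not stated in the files. With a total of 1e7 tags, HOMER's usual setting, the steps correspond to 25.2 to 58.1 units of 1e6 tags per library. All peaks of a list had 1 width, from 258 to 318 bp. The peak lists hold no values for places without a peak, so a site absent from a list is not shown to be unbound, and no fold change of binding was computed.

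Positions were set against the GRCh37 sequence, the same assembly as hg19, and GENCODE 44 lifted to it, with 19794 protein-coding genes and 78701 start sites, and no peak reached beyond a chromosome end. Peaks of an antibody's 6 libraries were merged where they overlapped by at least 1 bp, and a site was called in a group when at least 2 of its 3 libraries had a peak there. With 1 library left out, both remaining libraries of its group had to hold the site. Site bounds are those of the merged peaks of the group named. A pan-ER E2 site was pS118-positive when it overlapped E2 sites of at least 2 of the 3 pS118 antibodies. The rank of a peak is its percentile within its own list by normalized tag count, averaged over the libraries of a group that hold the site.

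Numbers of peaks were compared as mean log2 counts with exact two-sided permutation tests over all 20 splits of 6 libraries, which cannot give less than p = 0.1. Over 4 and over 3 antibodies together, labels were permuted within each antibody (160000 and 8000 combinations). Tests over antibodies, also with the replicate number as a block, take the libraries of different antibodies as independent. Differences among antibodies were tested by dividing 12 values into 4 groups of 3 in all 15400 distinct ways, with the share of variance between groups as the statistic. E2 and vehicle libraries were divided by replicate number there only to form separate ratios. Overlaps were tested one-sided against 1000 placements of the sites within their own chromosome, and ranks two-sided with 100000 resamples. Shares have 95% Wilson intervals, which cover counting error only.

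Motifs were searched on both strands within 100 bp of the midpoint of a site, a window of 201 bp. The full ERE was GGTCANNNTGACC with 1 mismatch allowed, and the others were matched exactly: AGGTCA for a single arm of the ERE, AACYKGTT for GRHL, TGTTTAC for FOXA, TGASTCA for AP-1, GCCNNNGGC for AP-2, AGATAAG for GATA and CCASYAGRKGGC for CTCF. Such patterns count matches to a consensus, not binding by the factor. Shares were compared with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the 8 motifs, and with windows 2 kb from the sites as background; p-values under 1e-300 were set to that floor. Matched odds ratios were Mantel-Haenszel estimates over strata of rank or GC content.

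For the 10 gene lists (164 genes: induced by estradiol, lowered by estradiol, luminal identity, epithelial junctions, coregulators of the receptor, cell cycle, housekeeping, mesenchymal or basal cells, neuron and muscle, blood cells), a gene counted as near when a site lay within 50 kb of one of its starts. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, adjusted over the 10 lists of each set of sites. Genes with more start sites or in gene-rich regions have more chances of a nearby site, and nearness does not show which gene a site acts on.

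The genes and sites named follow a rule. It takes up to 8 genes from each of the estradiol-induced, luminal, epithelial junction and coregulator lists, those whose nearest site within 50 kb was in the most pS118 E2 libraries, with ties broken by rank and then symbol. TFF1, GREB1, PGR, MYC, ESR1 and GRHL2 are always given. It also takes the 10 highest pan-ER E2 sites, the 10 highest among sites in the most pS118 E2 libraries, and 5 of each kind with vehicle; sites are named by the nearest protein-coding start. The groups, tests, gene lists, motifs, this rule and the first set of other settings were fixed before the data were examined.

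Other settings planned were the higher-scoring 50% of each list, overlap by 50% of the shorter peak, sites in 3 of 3 or 1 of 3 libraries, leaving out each library in turn, the replicate number as a block, untransformed counts, bases covered, standard chromosomes only, other definitions of the pS118-positive class, motif windows of 50 and 250 bp, 0 or 2 mismatches in the ERE, strata of rank and GC content, a promoter distance of 5 kb and gene distances of 20 and 100 kb. Added after the data were seen were a normalized tag count of at least 10, 50 strata of rank, also with pS118 vehicle sites left out, a class set by the Abcam antibody alone, placements 5 to 50 kb from each site, leaving out the Cell Signaling libraries, and gene lists near pS118 sites at pan-ER sites only. These used 200 placements and 2000 resamples.

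The overlap and motif steps were tested on simulated data. Of 4000 simulated sites, 75% were placed on another list and 75% were found there, and a motif planted in 20000 windows at an odds ratio of 2.67 was found at 2.59. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0, matplotlib 3.10.9 and samtools 1.23.1.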

Results

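Binding of the estrogen receptor ERα to DNA was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF-7, a human breast cancer cell line that carries the receptor. The cells were kept for 3 days in medium stripped of hormones and then given 10 nM 17β-estradiol (E2) or 0.01% ethanol (vehicle) for 30 min. Chromatin was recovered with 4 antibodies, one against all forms of the receptor (pan-ER, Santa Cruz) and 3 against its form phosphorylated at a serine of the N-terminal part (pS118, from Cell Signaling, Abcam and Santa Cruz). Each antibody was used in 3 E2 and 3 vehicle replicates, which gave 24 peak lists in 8 groups, and a vehicle input library was not analysed here. The low values of each list were whole multiples of 1 sequenced tag, which gives the number of tags per library up to a scaling total that the files do not state. With a total of 1e7 tags the depth per group, in units of 1e6 tags, was 33.7 ± 3.17 (SD, n = 3) for pan-ER E2 and 31.8 ± 2.45 for pan-ER vehicle. It was 33.3 ± 7.02 and 44.1 ± 14.3 for Cell Signaling E2 and vehicle, 40.7 ± 4.23 and 40.4 ± 3.89 for Abcam, and 39.2 ± 1.51 and 36.1 ± 8.78 for Santa Cruz pS118. The labels do not say whether replicates came from separate cultures, so p-values of peak numbers measure only the spread between these samples, which may be technical. Tests of motifs, ranks, overlaps, promoters and gene lists took single sites or genes as units. The spread between libraries does not enter their p-values. Peak heights are the authors' own values and were used to rank peaks within a list. Apart from that they gave the tag steps and, in an alternative setting, a cut at a normalized tag count of 10.

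The first comparison asked how many places in the genome each antibody recovered after 30 min of E2 and with vehicle. Pan-ER peaks numbered 56224 ± 581 with E2 and 24025 ± 2827 with vehicle (SD, n = 3 each), a 2.35-fold difference. Folds here are ratios of geometric means, that is, of mean log2 counts, and differ from the ratios of the arithmetic means printed beside them. Abcam pS118 peaks went from 335 ± 240 with vehicle to 5041 ± 2295 with E2, 16.5-fold, and Santa Cruz pS118 peaks from 4774 ± 3110 to 23052 ± 3466, 6.11-fold. Cell Signaling pS118 peaks numbered 4303 ± 675 with E2 and 3760 ± 232 with vehicle, 1.14-fold, and here the lists of both treatments overlapped in size. In log2 units the E2 to vehicle ratio of peak number was 1.23 for pan-ER, 4.04 for Abcam and 2.61 for Santa Cruz pS118 (exact two-sided permutation p = 0.1 each, the smallest that 3 against 3 libraries can give) and 0.18 for Cell Signaling (exact p = 0.2). Over the 4 antibodies together the mean log2 ratio was 2.02 (exact two-sided permutation within antibody, p = 2.5e-05), and over the 3 pS118 antibodies it was 2.28 (p = 5e-04 by the same exact test). Both tests take the libraries of different antibodies as independent. Whether antibodies shared chromatin was not established, and if they did, these p-values are too small. The response differed among antibodies, which accounted for a share of 0.755 of the variance of the replicate log2 ratios (exact permutation p = 0.0184), and the E2 peak numbers differed too (share 0.968, exact permutation p = 5.195e-04). Without the Cell Signaling libraries the first share was 0.596 (exact permutation p = 0.05), which ends that call. One Santa Cruz vehicle library, replicate 2, held 1231 peaks against 6033 and 7057 in the other two, and without it the Santa Cruz log2 ratio was 1.81. The Cell Signaling log2 ratio was 0.06 without E2 replicate 1.

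**Figure D1:**
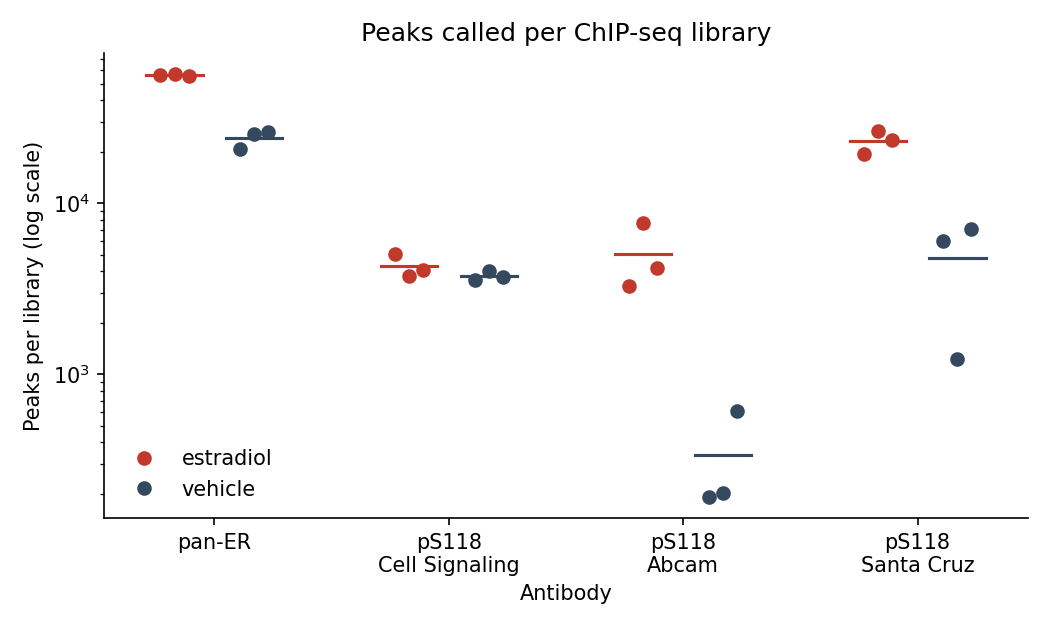
Number of peaks per library (vertical axis, log scale) for pan-ER and the 3 pS118 antibodies with vehicle and with E2. Each point is 1 library and each short line a mean (n = 3). Abcam pS118 lists held 191 to 612 peaks with vehicle and 3300 to 7642 with E2, while Cell Signaling lists held 3563 to 4016 and 3770 to 5062.

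Peaks of an antibody that overlapped were joined into sites, and a site was called in a group when at least 2 of its 3 libraries held it. Pan-ER sites numbered 54830 with E2 and 22331 with vehicle, of which 19985 were called in both, 34845 only with E2 and 2346 only with vehicle. Receptor binding after E2 therefore took in 89.5% of the pan-ER sites already present without hormone. The Abcam pS118 antibody gave 4047 E2 sites and 78 vehicle sites, 75 of them shared, and the Santa Cruz pS118 antibody gave 20506 and 3397, with 3001 shared. The Cell Signaling pS118 antibody gave 3610 E2 and 3088 vehicle sites with 1867 shared, so that 1743 were called only with E2 and 1221 only with vehicle. A stricter count took sites present in all 3 E2 libraries and in no vehicle library. It found 21160 for pan-ER, 715 for Cell Signaling, 2108 for Abcam and 9474 for Santa Cruz pS118, against 426, 153, 0 and 6 in the opposite direction. Replicate lists of a group shared 85.3% of the smaller list on average for pan-ER E2, 81.1% for pan-ER vehicle, 78.6% and 26.5% for Abcam E2 and vehicle, 78.0% and 70.0% for Santa Cruz, and 66.1% and 58.5% for Cell Signaling. These shares can be higher where lists differ in size. Santa Cruz vehicle replicates 1 and 3 shared 53.0%, and the small replicate 2 shared 78.1% and 78.7% with them. By shared over joint bases (mean Jaccard index), Santa Cruz vehicle lists gave 0.161 and Cell Signaling vehicle lists 0.276. With 1 library left out, a site needed both remaining libraries of that group but still 2 of 3 in the other. The shifts that follow thus arise partly by construction. The 2346 pan-ER sites called only with vehicle were 1105 and 1229 without vehicle replicate 2 or 3 and 3687 and 3752 without E2 replicate 1 or 2. For Cell Signaling the order turned without any 1 of the E2 libraries, when its E2 sites numbered 2419 to 2691, below the 3088 vehicle sites. Without E2 replicate 1, 1081 sites were called only with E2 and 1747 only with vehicle. Its E2-only sites were 1134 without E2 replicate 3, and its vehicle-only sites were 652, 584 and 737 without vehicle replicate 1, 2 or 3. The 3088 Cell Signaling vehicle sites were 2027 without vehicle replicate 2. The Abcam sites called only with E2, 3972 in all, fell to 2209 without E2 replicate 2 and to 2365 without E2 replicate 3, and the 4047 E2 sites to 2284 and 2440. The 78 Abcam vehicle sites fell to 41 and 42 without vehicle replicate 2 or 3, and the 75 shared sites to 41 in both cases. Santa Cruz vehicle sites fell to 973 and 968 without vehicle replicate 1 or 3, and the shared sites to 933 and 927.

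The second comparison asked where phosphorylated receptor lay relative to all receptor after E2. Of the 4047 Abcam pS118 E2 sites, 4042 overlapped a pan-ER E2 site (99.9%, 95% Wilson interval 99.7 to 99.9), and 18762 of the 20506 Santa Cruz pS118 sites did so (91.5%, interval 91.1 to 91.9). The Cell Signaling antibody differed, with 1764 of 3610 sites at a pan-ER site (48.9%, interval 47.2 to 50.5). Sites placed at random within their chromosome overlapped pan-ER sites in 1.43% of cases for Cell Signaling, 1.26% for Abcam and 1.31% for Santa Cruz on average over 1000 placements. Each one-sided permutation p was 9.99e-04, the smallest that these placements can give, also after Benjamini-Hochberg adjustment. Placed instead 5 to 50 kb from where they were, the sites overlapped pan-ER sites in 2.97%, 3.07% and 2.60% of cases (one-sided permutation p = 0.00498 each, the smallest that 200 placements can give). Among the pS118 antibodies, 99.6% of Abcam sites were Santa Cruz sites, 57.3% of Cell Signaling sites were Santa Cruz sites and 29.3% of Cell Signaling sites were Abcam sites, each with a permutation p of 9.99e-04 from 1000 placements. The intervals cover counting error only. Single Abcam lists, before sites were called, overlapped pan-ER less completely. Of the peaks of Abcam E2 replicate 1, 75.6% to 75.8% overlapped a peak of a pan-ER E2 library, against 95.1% to 96.7% for replicates 2 and 3.

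Seen from the pan-ER list, 35958 of the 54830 E2 sites (65.6%) carried no pS118 antibody, 14230 carried 1, 3588 carried 2 and 1054 carried all 3. The median pan-ER rank percentile, on which 100 is the highest peak of a list, was 35.4, 77.4, 93.6 and 98.7 in that order. In the top decile of pan-ER rank, 97.4% of sites were Santa Cruz pS118 sites, 62.4% were Abcam sites and 21.6% were Cell Signaling sites. In the lowest decile those shares were 1.37%, 0 and 0.42%. The 4642 sites with at least 2 pS118 antibodies, called pS118-positive from here on, had a median rank percentile of 95.2 against 46.8 for the other 50188 sites, a difference of 48.4 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The pS118 antibodies called fewer sites than pan-ER, and a list with fewer sites may hold mainly the strongest. The difference thus does not show whether receptor was phosphorylated more often at high sites.

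**Figure D2:**
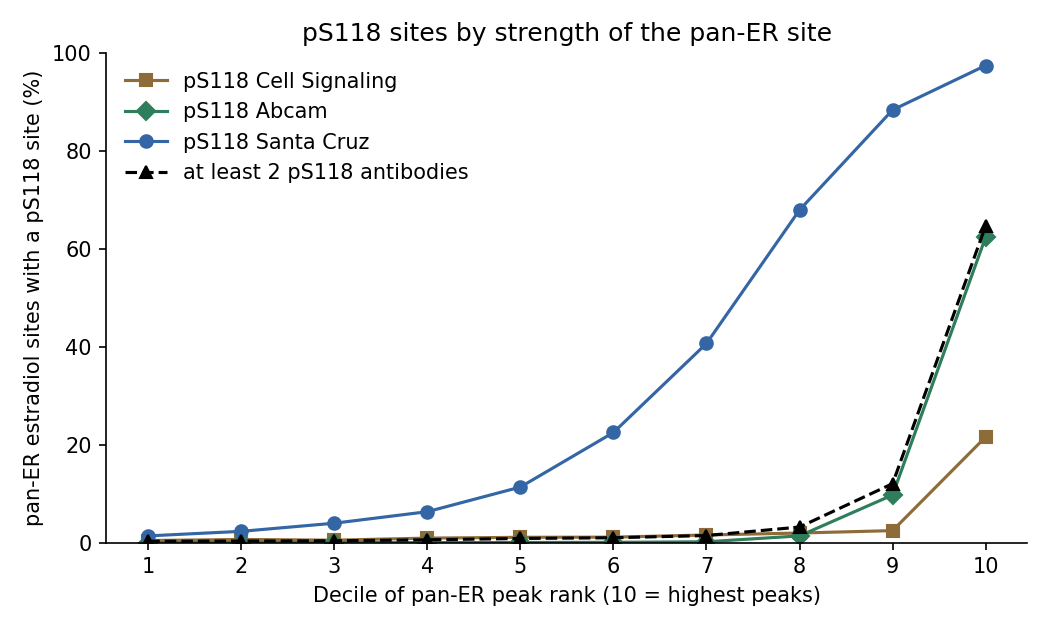
Percentage of pan-ER E2 sites that were also pS118 E2 sites (vertical axis) by decile of pan-ER peak rank (horizontal axis, 10 = highest peaks), with 1 line per pS118 antibody and a dashed line for at least 2 of them. The Santa Cruz line reached 97.4% in the top decile, Abcam 62.4% and Cell Signaling 21.6%.

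Genes that estradiol is known to induce lay close to pS118 sites. Of a fixed list of 30 such genes, 24 (80.0%) had a site of at least 2 pS118 antibodies within 50 kb of a transcription start site (TSS), against 23.9% of the other 19764 protein-coding genes (odds ratio 12.7, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1.607e-09 over 10 lists). At 14 of the 24 the nearest site also had a peak in a pS118 vehicle library. Of all 5041 sites of at least 2 pS118 antibodies, 4651 lay at pan-ER E2 sites. No comparison with equally high pan-ER sites was made, so nearness to the phosphorylated form in particular is not shown. TFF1, a secreted mucosal peptide and a standard marker of receptor activity, had a site across its start (hg19 chromosome 21, 43786643 to 43787036). A peak was there in 3 of 3 Abcam, 3 of 3 Santa Cruz and 0 of 3 Cell Signaling E2 libraries, and in 2 Santa Cruz vehicle libraries. GREB1, an early estrogen-induced gene, had 7 pS118 sites and 18 pan-ER sites within that distance. Its intronic site on chromosome 2 (11638707 to 11639011) was among the 10 highest pan-ER sites and was held by all 9 pS118 E2 libraries and 4 vehicle libraries. A second intronic site (11679650 to 11679979), at an annotated start, was held by 6 and 3. PGR, the progesterone receptor, had an intronic site 48231 bp downstream of its nearest start (chromosome 11, 100949208 to 100949588) in 7 of the 9 pS118 E2 libraries. XBP1, a factor of the unfolded protein response, CTSD, the protease cathepsin D, PDZK1, a scaffold protein, and SGK3, a kinase, each had a nearest site held by all 9. EGR3, an immediate early factor, and IGFBP4, which binds insulin-like growth factors, had sites held by 8, and ABCA3, a lipid transporter, by 7. Near the oncogene MYC no pS118 site lay within 50 kb, and its nearest pan-ER site, 8496 bp upstream (chromosome 8, 128738841 to 128739184), had a peak in 1 pS118 E2 library. In the 260 kb around GREB1 (chromosome 2, 11572467 to 11832914), pan-ER lists held 18.3 ± 0.577 peaks with E2 and 12.7 ± 1.53 with vehicle (SD, n = 3). Abcam lists held 7 in each E2 library and 0.667 ± 1.15 with vehicle. Santa Cruz lists held 8.33 ± 0.577 and 5.33 ± 1.53, and Cell Signaling lists 4 in each E2 library and 1.33 ± 0.577 with vehicle.

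**Figure D3:**
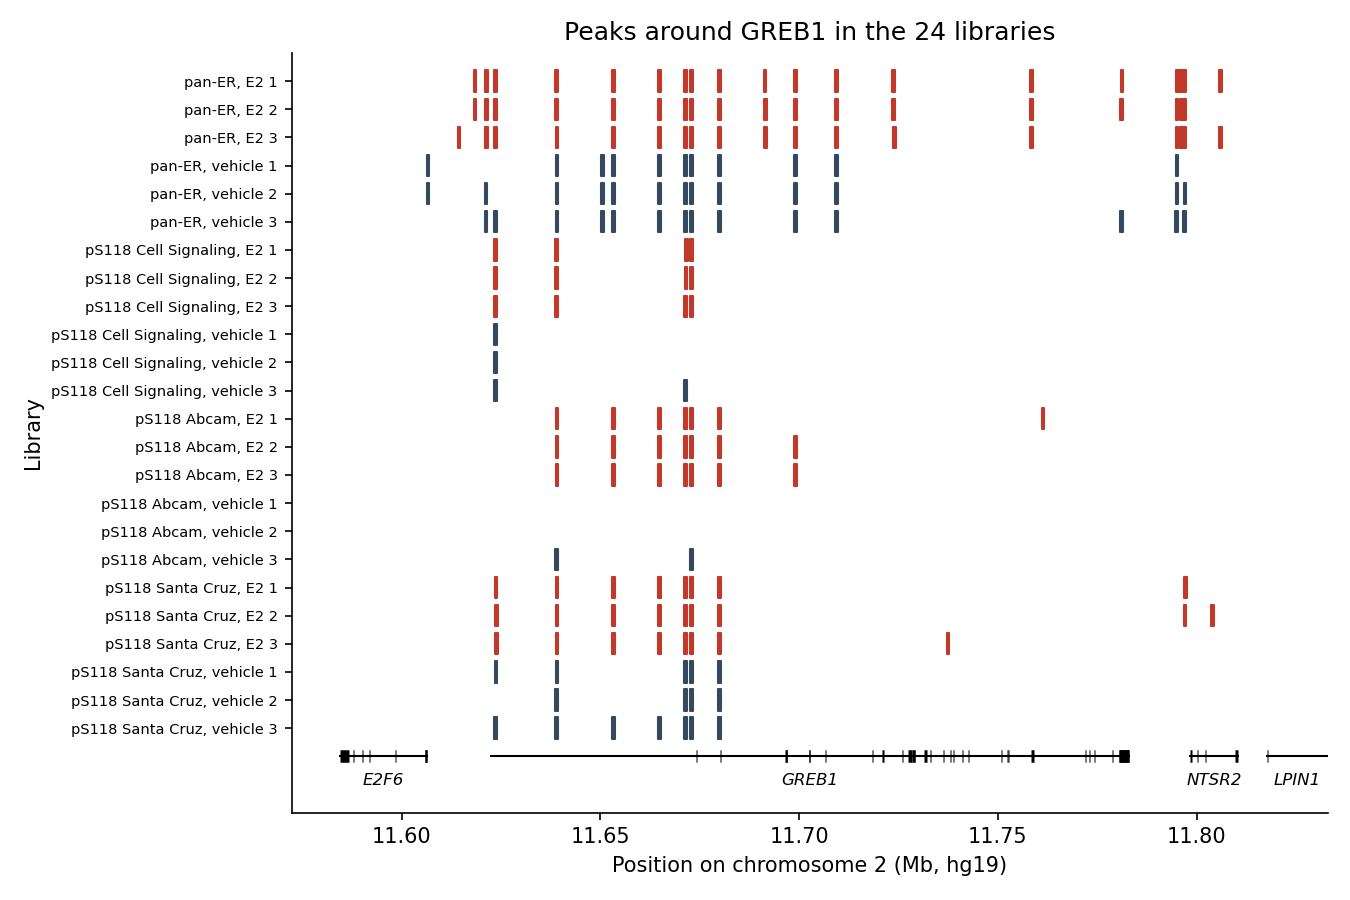
Peaks of the 24 libraries (1 line each, E2 in red, vehicle in blue) along chromosome 2 around GREB1 (hg19, position in Mb), with the exons of E2F6, GREB1, NTSR2 and LPIN1 below; peaks are drawn wider than they are so that they show. All 3 Abcam E2 libraries held 7 peaks each, and the 3 Abcam vehicle libraries held 0, 0 and 2.

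Genes of luminal breast identity were near pS118 sites as well, 13 of 20 within 50 kb (65.0%, odds ratio 5.89, Fisher's exact adjusted p = 5.853e-04). GRHL2, a grainyhead-like factor of epithelial cells, had an intronic site 11346 bp downstream of a start (chromosome 8, 102516332 to 102516645) with a pan-ER rank percentile of 99.96. It was held by 3 of 3 Abcam and 3 of 3 Santa Cruz E2 libraries and by no pS118 vehicle library. ESR1, the gene of the receptor itself, had a site 134 bp upstream of a start, within an intron of its longer transcripts (chromosome 6, 152010887 to 152011497). It had peaks in 3 Cell Signaling and 3 Santa Cruz but 0 Abcam E2 libraries, and in 3 Cell Signaling and 2 Santa Cruz vehicle libraries. The sites nearest KRT18 and KRT19, keratins of luminal cells, were held by all 9 pS118 E2 libraries and by 3 and 7 vehicle libraries. TFAP2C, an AP-2 factor, PRLR, the prolactin receptor, AGR2, a protein of the secretory pathway, and TRPS1, a GATA-type repressor, each had a nearest site held by 6 E2 libraries.

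Of 21 genes of epithelial junctions and surface proteins, 11 had a pS118 site within 50 kb (52.4%, odds ratio 3.49, Fisher's exact adjusted p = 0.0257). At 5 of these 11 the nearest pS118 site had no pan-ER E2 peak. They included CLDN4, a claudin of tight junctions, whose site in its untranslated region (chromosome 7, 73246267 to 73246887) was held by 3 of 3 Cell Signaling libraries with E2 and by 3 with vehicle. The nearest sites of CLDN7, PRSS8 and ERBB3 lay at the starts of the neighbouring genes GABARAP, FUS and RPL41. CDH1, which encodes E-cadherin, had an intronic site (chromosome 16, 68779571 to 68779932) held by 3 pan-ER, 3 Abcam and 3 Santa Cruz E2 libraries and by no pS118 vehicle library. TJP3, a tight junction scaffold, had a site held by all 9 pS118 E2 libraries, and SPINT1 and SPINT2, protease inhibitors of the epithelial surface, had sites held by 6. With pS118 sites away from pan-ER sites left out, the excess of this list over other genes fell from 28.4 to 13.3 percentage points (exact adjusted p = 0.278 by Fisher's exact test), which ends the call. So does asking for 3 of 3 libraries (18.9 points, exact adjusted p = 0.0806).

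The other 7 lists did not pass the test near pS118 E2 sites. Coregulators of the receptor had 6 of 16 genes (37.5%), among them the corepressors NCOR1, NCOR2 and NRIP1 with sites held by 6, 7 and 6 pS118 E2 libraries. The others were PRMT1, an arginine methyltransferase, DDX17, a helicase, and KMT2D, a histone methyltransferase whose nearest site had no pan-ER peak. Genes lowered by estradiol had 4 of 10, housekeeping genes 5 of 12, and the adjusted p was 0.332 for each of these 3 lists (Fisher's exact test). Cell cycle genes and genes of mesenchymal or basal cells had 3 of 15 each (exact adjusted p = 1), neuron and muscle genes 1 of 14 (exact adjusted p = 0.332) and blood cell genes 0 of 12 (exact adjusted p = 0.206). Near pan-ER E2 sites lay 81.5% of all other genes, and there the estradiol-induced list alone passed, with 30 of 30 genes (Fisher's exact adjusted p = 0.0363, and 0.791 at 100 kb). The luminal, epithelial and coregulator lists had 20 of 20, 21 of 21 and 16 of 16 genes near pan-ER E2 sites. Genes lowered by estradiol had 10 of 10, cell cycle genes 13 of 15 and housekeeping genes 10 of 12. Mesenchymal or basal genes had 14 of 15, neuron and muscle genes 12 of 14 and blood cell genes 8 of 12.

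The 10 highest pan-ER E2 sites were each held by all 9 pS118 E2 libraries and were also the 10 highest by pS118 rank among the 663 sites held by all 9. The first lay 404184 bp downstream of MYC and outside any annotated protein-coding gene (chromosome 8, 129154175 to 129154477). It carried a full estrogen response element (ERE) and a GRHL motif, and was held by 6 pS118 vehicle libraries. Others lay in introns of TEX14, a gene of germ cell bridges, of BRIP1, a DNA repair helicase, and of GREB1. The rest had as their nearest gene PARD6B, a cell polarity gene, PFDN4, a prefoldin subunit, PRLH, a prolactin-releasing hormone, MED13L, a Mediator subunit, TSKU, which encodes a secreted protein, and STARD10, a lipid transfer protein. A full ERE lay in 8 of the 10. With vehicle, the 5 highest pan-ER sites were those named above for MYC, TEX14, MED13L and BRIP1 and 1 in an intron of ATRNL1. Each lay over 50 kb from its nearest start, from 52027 bp (TEX14) to 404199 bp (MYC). Only 3 sites were held by every pS118 vehicle library. Their nearest starts were those of EPS15L1 (7665 bp away), NYAP2 (568251 bp) and GALNT4 (59484 bp).

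The title of the study names direct receptor binding to DNA and GRHL2, so motifs were compared between pS118-positive and other pan-ER E2 sites, within 100 bp of the site centre. A full ERE, the palindrome that the receptor dimer contacts, lay in 36.0% of the 4642 pS118-positive sites and in 12.5% of the 50188 others (odds ratio 3.94, 95% interval 3.69 to 4.21, two-sided Fisher's exact adjusted p no higher than 8e-300, from a floor of 1e-300). A single arm of the ERE lay in 59.8% and 46.7% (odds ratio 1.70, exact adjusted p = 2.443e-65). The GRHL motif lay in 6.89% and 5.19% (odds ratio 1.35, interval 1.20 to 1.53, exact adjusted p = 5.313e-06), and the AP-2 motif in 9.72% and 8.49% (odds ratio 1.16, exact adjusted p = 0.00697). Motifs of FOXA factors, which open chromatin for the receptor, were rarer at pS118-positive sites, 6.74% against 8.06% (odds ratio 0.825, exact adjusted p = 0.00259). So were GATA motifs, 6.18% against 7.43% (odds ratio 0.821, exact adjusted p = 0.00259). AP-1 motifs (odds ratio 1.08, exact adjusted p = 0.185) and CTCF motifs (odds ratio 1.08, exact adjusted p = 0.744) did not pass. The AP-1 excess passed when any 1 antibody (odds ratio 1.17, Fisher's exact adjusted p = 1.098e-05) or the Santa Cruz antibody set the class (1.17, adjusted p = 7.663e-06), and was 0.888 within deciles of pan-ER rank. Sites with 0, 1, 2 and 3 pS118 antibodies carried a full ERE in 11.9%, 14.0%, 34.3% and 41.8% of cases and a GRHL motif in 4.36%, 7.28%, 6.61% and 7.87%. Windows 2 kb from the sites carried them in 0.505% and 2.07%. Of the 14230 sites with 1 antibody, 14120 had the Santa Cruz one alone, and these count among the 50188 others. Among E2 sites of each pS118 antibody at pan-ER sites, a full ERE lay in 41.3% for Abcam, 19.0% for Santa Cruz and 21.4% for Cell Signaling. The size of the ERE excess thus depended on how the class was set. The GRHL odds ratio was 0.843 (exact adjusted p = 0.146) once pan-ER sites that were also pS118 vehicle sites were left out and 0.987 (exact adjusted p = 0.907) when the Abcam antibody alone set the class, so that its direction depended on these choices. Within 50 strata of pan-ER rank and without those vehicle sites it was 0.681 (interval 0.528 to 0.879). The FOXA odds ratio was 1.04 when any 1 pS118 antibody or the Santa Cruz antibody set the class. The FOXA call also ended within deciles of GC content (odds ratio 0.945) and with all 3 antibodies (0.95, Fisher's exact adjusted p = 0.730). The GATA call ended within deciles of GC content (odds ratio 0.932). It also ended without the pS118 vehicle sites (0.939, Fisher's exact adjusted p = 0.468), in the Abcam class (0.915, exact adjusted p = 0.284), with all 3 antibodies (0.747, exact adjusted p = 0.0501) and in windows of 50 bp (0.848, exact adjusted p = 0.0678). The AP-2 odds ratio was 0.910 within deciles of GC content and 0.954 within deciles of pan-ER rank. Its call also ended without the pS118 vehicle sites (1.03, exact adjusted p = 0.709) and in windows of 50 bp (1.15, exact adjusted p = 0.0694). It ended as well without pan-ER E2 replicate 2 or Cell Signaling E2 replicate 1 or 3 (exact adjusted p = 0.0793, 0.0841 and 0.0884).

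**Figure D4:**
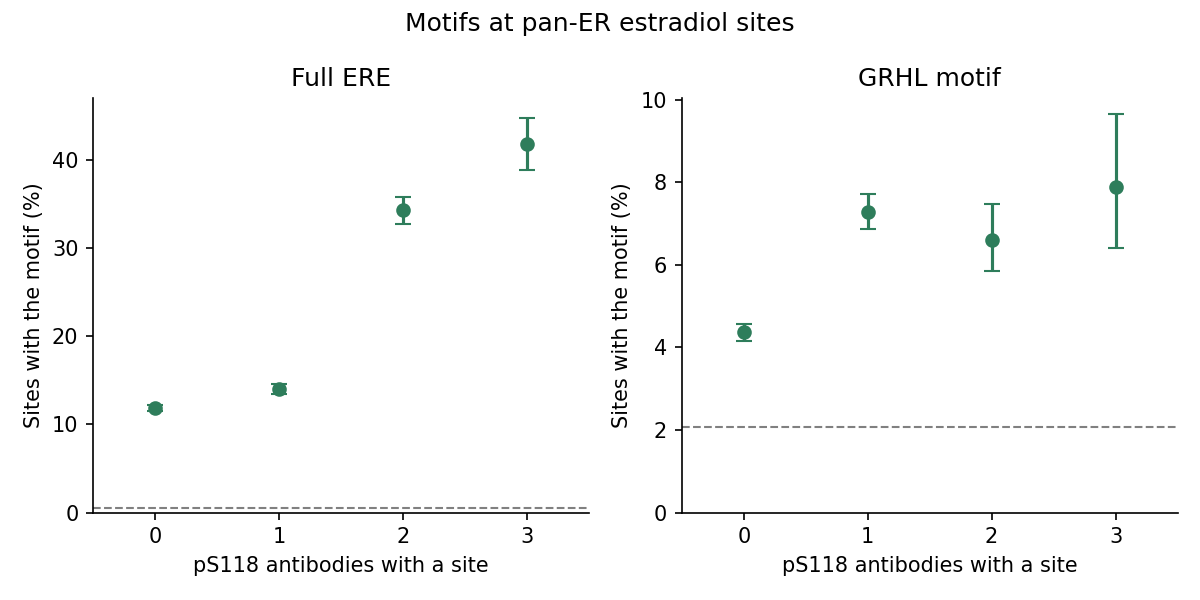
Percentage of pan-ER E2 sites with a full ERE (left) or a GRHL motif (right) within 100 bp of the centre (vertical axis). Sites are grouped by number of pS118 antibodies (0 to 3), with 95% Wilson intervals and a dashed line for windows 2 kb away. The full ERE went from 11.9% at sites with none to 41.8% at sites with 3, and the GRHL motif from 4.36% to 7.87%.

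Promoters held a small part of both classes. Within 1 kb of a protein-coding TSS lay 334 pS118-positive sites (7.20%) and 2630 of the others (5.24%), an odds ratio of 1.40 (interval 1.25 to 1.58, two-sided Fisher's exact p = 6.457e-08). The direction was the opposite when all 3 pS118 antibodies were asked for (odds ratio 0.777, Fisher's exact p = 0.113) or the Abcam antibody alone (0.904, p = 0.193). Among all sites of each pS118 antibody, 39.8% of Cell Signaling, 4.99% of Abcam and 8.50% of Santa Cruz E2 sites lay within 1 kb of a TSS. With vehicle the shares were 56.1%, 2.56% and 15.9%. Santa Cruz sites away from any pan-ER site were also rich in promoters, 34.8% of 1438 with E2 and 35.8% of 838 with vehicle.

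Without hormone, pan-ER sites already lay within 50 kb of 29 of the 30 estradiol-induced genes (96.7% against 55.7% of other genes, odds ratio 23.1, Fisher's exact adjusted p = 7.979e-06). The same held for genes lowered by estradiol (10 of 10, exact adjusted p = 0.0158), luminal genes (17 of 20, 0.0224) and epithelial junction genes (18 of 21, 0.0193). Blood cell genes were less often near such sites (2 of 12, odds ratio 0.159, exact adjusted p = 0.0193). Coregulators (13 of 16, exact adjusted p = 0.0746), cell cycle (8 of 15), housekeeping (7 of 12), mesenchymal or basal (8 of 15) and neuron and muscle genes (5 of 14) did not pass Fisher's exact test. Without pan-ER vehicle replicate 2 or 3 the calls for genes lowered by estradiol (exact adjusted p = 0.131 and 0.107) and for epithelial junction genes (0.159 and 0.0705) ended. Both also ended in 3 of 3 libraries (Fisher's exact adjusted p = 0.0690 and 0.0952) and at 100 kb (0.176 and 0.12). The luminal call ended at 100 kb (exact adjusted p = 0.125). The blood cell call ended with a normalized tag count of at least 10 (exact adjusted p = 0.232), in 3 of 3 libraries (0.0541), at 20 kb (0.138) and at 100 kb (0.335). Santa Cruz pS118 vehicle sites lay near 14 of 21 epithelial junction genes (odds ratio 7.45, Fisher's exact adjusted p = 9.212e-05), 16 of 30 estradiol-induced genes (odds ratio 4.26, 5.457e-04), 12 of 20 luminal genes (5.58, 6.113e-04) and 8 of 16 coregulators (3.72, 0.0252). Of these 4 calls, the epithelial one (exact adjusted p = 0.128 and 0.138) and the coregulator one (1 and 0.886) ended without Santa Cruz vehicle replicate 1 or 3. Both also ended in 3 of 3 libraries (exact adjusted p = 0.0979 and 1), and the coregulator call with a normalized tag count of at least 10 (0.362) and at 20 kb (0.199). The luminal excess fell from 38.8 percentage points to a lowest value of 18.6, without vehicle replicate 3 (exact adjusted p = 0.0366). Cell Signaling pS118 vehicle sites lay near 16 of 21 epithelial junction genes (odds ratio 8.02, Fisher's exact adjusted p = 8.295e-05) and near 7 of 30 estradiol-induced genes, 23.3% against 28.6% of other genes. They also lay near 7 of 12 housekeeping genes (odds ratio 3.50, Fisher's exact adjusted p = 0.158). Of the 3088 Cell Signaling vehicle sites, 2170 lay away from any pan-ER site and 56.1% within 1 kb of a TSS. The epithelial excess fell from 47.7 points to a lowest value of 29.6, without vehicle replicate 3 (exact adjusted p = 0.0302). No gene of mesenchymal or basal cells (0 of 15, exact adjusted p = 0.0443) had such a site, a call that ended without any 1 of the 3 vehicle libraries (exact adjusted p = 0.0902 to 0.132). It also ended with a normalized tag count of at least 10 (exact adjusted p = 0.151), in 3 of 3 libraries (0.224), at 20 kb (0.226) and at 100 kb (0.183). The 78 Abcam vehicle sites lay near 2 of the 30 estradiol-induced genes (odds ratio 28.2, Fisher's exact adjusted p = 0.0281), which ended without vehicle replicate 1 or 3 (0.351 and 0.149). It also ended in 3 of 3 libraries (exact adjusted p = 0.135), at 20 kb (0.314) and at 100 kb (0.0560).

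As a technical check, the share of peaks on chromosomes 1, 17 and 20, which carry gains in MCF-7, was compared between treatments. It was 14.0% ± 0.263 with E2 and 12.9% ± 0.434 with vehicle for pan-ER, and 13% ± 0.764 and 9.59% ± 1.18 for Abcam. The shares were 14.5% ± 0.235 and 15.3% ± 1.08 for Santa Cruz, and 17.6% ± 0.304 and 18.4% ± 0.489 for Cell Signaling pS118 (SD, n = 3 each). The exact two-sided permutation p was 0.1 for pan-ER and Abcam, 0.4 for Santa Cruz and 0.2 for Cell Signaling, where 0.1 is the smallest possible. Both treatments used the same cell line, so the comparison can neither show nor exclude an effect of copy number on the peaks.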

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

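The tests of the Cell Signaling sites and of the motif classes within 50 strata were chosen only after seeing the result, the tests of the classes by GC content and by vehicle sites were planned but read against bounds set after it, and the splits were set before.

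The E2 response in number of peaks differed among the 4 antibodies, with a share of 0.755 of the variance of the replicate log2 ratios lying between them (exact permutation p = 0.0184). The mean log2 ratio was 4.04 for Abcam, 2.61 for Santa Cruz, 1.23 for pan-ER and 0.18 for Cell Signaling. As given above, the call of a difference ended without the Cell Signaling libraries.

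The Cell Signaling pS118 antibody gave 1711 E2 sites away from any pan-ER peak site. Of these, 72.7% (95% interval 70.5 to 74.8) were also Cell Signaling vehicle sites, and their share within 1 kb of a TSS was 12 times that of pan-ER E2 sites (64.9% against 5.41%). A full ERE lay in 0.468% of them (interval 0.237 to 0.920), close to the 0.505% of windows 2 kb from pan-ER sites and far below the 11.9% of pan-ER sites without any pS118 antibody, which argues against receptor bound to EREs that the pan-ER antibody missed. These values are consistent with recovery of promoter chromatin that does not depend on estradiol, and whether another phosphorylated protein or open chromatin is the source stays open. Apart from receptor at such EREs, no biological explanation of these sites was tested.

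For the full ERE at pS118-positive against other pan-ER sites, the odds ratio was 4.47 (interval 4.00 to 5.00) within 50 strata of pan-ER rank, 3.63 (3.40 to 3.88) within deciles of GC content and 4.65 (4.30 to 5.02) without sites held by a pS118 antibody with vehicle (7.07, 6.19 to 8.08, with rank strata as well), so that none of these 3 is the whole cause. What else is involved stays open. For the GRHL motif, rank and GC content did not account for the excess either (odds ratios 1.36, interval 1.15 to 1.62, and 1.41, 1.25 to 1.59), but without pan-ER sites held by a pS118 antibody with vehicle it was 0.843 (0.702 to 1.01), and 0.681 (0.528 to 0.879) within the rank strata as well. GRHL motifs lay in 11.9% of pS118-positive sites held with vehicle and in 18.3% of other pan-ER sites held with vehicle, against 4.17% and 4.90% of those without a vehicle site. The excess over all sites was thus seen in neither part, and it may reflect that more pS118-positive sites were already recovered without hormone.

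Sites in all 3 E2 and in no vehicle library numbered 33457 over the 4 antibodies. Of all within-antibody splits, 100 were used, the real one and others drawn at random, with the opposite labelling taken as the same split, and the highest of these others gave 30664. The real split was the only 1 of the 100 with as many, which argues against a chance division as the source of this sum. That holds only if the antibodies are independent. The sum rests mostly on pan-ER and Santa Cruz and says little of Cell Signaling and Abcam. Within each antibody there are 10 splits, with the opposite labelling again taken as the same, and 10 splits cannot give a share under 0.05. The real values were 21160 for pan-ER, 715 for Cell Signaling, 2108 for Abcam and 9474 for Santa Cruz, and the highest of the other splits gave 322, 82, 1 and 206, with 1 split of each reaching the real value.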

How the results depend on the processing

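The tests with a normalized tag count of at least 10, 50 strata of rank, the Abcam class, nearby placements, no Cell Signaling libraries and pS118 sites at pan-ER sites only were chosen after the data were seen.

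Over 123 results and 1075 alternative values, the log2 ratios of peak number over 4 and over 3 antibodies together, the difference among antibodies in E2 peaks, the overlaps with pan-ER sites and between pS118 antibodies, the rank difference and the full ERE excess kept their direction and their side of the threshold under every alternative run. The ratios of single antibodies kept their direction, but no p under 0.1 is possible for them, so their side of the threshold shows nothing. With the replicate block (sign flips per replicate number) the 4 antibodies together gave 2.02 (exact p = 9.766e-04) and the 3 pS118 antibodies 2.28 (exact p = 0.0078); for single antibodies the paired ratios were 1.23, 0.18, 4.04 and 2.61 with exact p from 0.25 to 0.5, where 0.25 is the smallest possible. Same-numbered libraries showed no strong pairing, but a weak one cannot be excluded. Over 12 pairs of same-numbered libraries the correlation of deviations ran from -0.0653 to 0.118 and 1 was over 0.1. In 8 of the 12 pairs the own number correlated best. Keeping the higher-scoring 50% of each list leaves ratios of peak numbers as they are, so it was not run for them.

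Counts of sites moved with the definition; fewer or more peaks or libraries enter by construction. Sites called only with E2 and only with vehicle were 17068 and 942 (pan-ER), 943 and 668 (Cell Signaling), 2152 and 0 (Abcam), and 9361 and 244 (Santa Cruz) in the higher-scoring 50%. In 1 of 3 libraries the vehicle-only count was 6016 for pan-ER, and the E2-only and vehicle-only counts were 3645 and 2939, 8623 and 712, and 27596 and 3048 for the others in the same order. In 3 of 3 libraries they were 1120 and 721 for Cell Signaling and 2238 and 0 for Abcam, with 1537 and 54 vehicle-only for pan-ER and Santa Cruz. With a tag count of at least 10, vehicle-only sites were 1093, 754, 0 and 254. Sites in all 3 E2 and no vehicle library were 11856, 458, 1337 and 5709 in the higher-scoring 50%. Leaving out 1 library, vehicle-only sites ranged from 1105 to 3752 for pan-ER (extremes without vehicle replicate 2 and E2 replicate 2), 584 to 1747 for Cell Signaling (without vehicle replicate 2 and E2 replicate 1), 0 to 3 for Abcam (lowest without vehicle replicate 2) and 40 to 698 for Santa Cruz (without vehicle replicate 1 and E2 replicate 2), and E2-only sites from 1081 to 2164 for Cell Signaling (without E2 replicate 1 and vehicle replicate 2) and 2209 to 4006 for Abcam (without E2 replicate 2 and vehicle replicate 2).

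The difference among antibodies in E2 response was 0.596 without the Cell Signaling libraries, where fewer values enter. Odds ratios that reversed were, for GRHL, 0.987 in the Abcam class and 0.843 without pS118 vehicle sites; for FOXA, 1.04 in the class of any antibody and 1.04 in the Santa Cruz class; for AP-1, 0.938 with 50 bp, 0.888 within rank deciles and 0.884 within 50 strata, against 1.17 and past the threshold in the classes of any antibody and of Santa Cruz; for AP-2, 0.992 in the Abcam class, 0.954 within rank deciles, 0.927 within 50 strata and 0.910 within GC deciles; for CTCF, 0.938 with a tag count of at least 10, 0 with all 3 antibodies, 0.901 and 0.918 with 50 and 250 bp and 0.857 within GC deciles; and for nearness to a TSS, 0.777 with all 3 antibodies and 0.904 in the Abcam class. The cause was not tested. Leaving out 1 library, AP-1 ranged from 0.966 to 1.12 and CTCF from 0.887 to 1.28, with the lowest values without Abcam E2 replicate 3 and 2.

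Near pS118 E2 sites, the epithelial list exceeded other genes by 18.9 points in 3 of 3 libraries and 13.3 with pS118 sites at pan-ER sites only, and neither passed the threshold. The coregulators were at -0.224 points at 100 kb, cell cycle genes at 2.31 with a tag count of at least 10 and 5.50 in 3 of 3, and housekeeping genes at -6.17 in 3 of 3; near Santa Cruz vehicle sites the coregulators were at -5.73 in 3 of 3. Leaving out 1 library gave -3.57 to 0.555 for cell cycle genes (highest without Abcam E2 replicate 2) and -6.40 to 29.8 for those coregulators, the lowest without vehicle replicate 3. Lists past the threshold near pan-ER E2 sites were 2 with a tag count of at least 10, 3 at 20 kb and 0 at 100 kb; near pan-ER vehicle sites 2 in 3 of 3 and 1 at 100 kb; near Cell Signaling vehicle sites 1 at 20 kb and 1 at 100 kb; near Abcam vehicle sites 0 in 3 of 3, 0 at 20 kb and 0 at 100 kb; and near Santa Cruz vehicle sites 2 in 3 of 3. Without 1 library they ranged from 1 to 2 (highest without E2 replicate 2), 3 to 5 (lowest without vehicle replicate 2), 1 to 2 (lowest without vehicle replicate 2), 0 to 1 (lowest without vehicle replicate 1) and 2 to 4 (lowest without vehicle replicate 1) in that order. The cause was not tested. Of the other results, alternatives apart from left-out libraries gave 203 values in the same state, 50 moved, 29 below the threshold, 2 newly past it and 19 reversed, and left-out libraries gave 205 in the same state, 19 moved, 14 below the threshold and 8 reversed. Lowest peaks of 11 to 20 tags limit what can be said of the weakest sites.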

Other observations

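The motif tests of pan-ER sites by treatment and of Santa Cruz vehicle sites were chosen only after seeing the data, and what each of the 3 further tests of the latter would show was written down before it was run.

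Pan-ER sites called only with E2 differed in motifs from the 19985 sites called with both treatments. Among the 34845 E2-only sites a full ERE lay in 15.6% against 12.6% (odds ratio 1.28, two-sided Fisher's exact, Benjamini-Hochberg adjusted p = 1.454e-21 over 8 motifs), and a single arm of the ERE in 52.2% against 40.1% (odds ratio 1.63, adjusted p = 9.133e-163). Other motifs were rarer there: FOXA 6.14% against 11.1% (odds ratio 0.524, Fisher's exact adjusted p = 8.944e-91), GRHL 4.19% against 7.33% (0.553, adjusted p = 2.267e-53), GATA 6.45% against 8.85% (0.709, adjusted p = 1.573e-24) and AP-1 6.78% against 7.84% (0.855, adjusted p = 5.777e-06). The median E2 rank percentile was 37.3 at E2-only and 76.5 at shared sites, and within 50 strata of that rank the odds ratios were 3.13 for the full ERE, 0.438 for FOXA, 0.499 for GRHL, 0.631 for GATA and 0.916 for AP-1. The AP-2 motif did not pass (odds ratio 1.02, Fisher's exact adjusted p = 0.601) and was more frequent at E2-only sites within the strata (1.21). The 2346 sites called only with vehicle carried a full ERE in 0.426% and lay within 1 kb of a TSS in 20.2%, and this set ranged from 1105 sites without vehicle replicate 2 to 3752 without E2 replicate 2. Of the 78 Abcam vehicle sites, 59 carried a full ERE (75.6%, interval 65.1 to 83.8), and without vehicle replicate 2 or 3 only 41 and 42 sites were called.

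Without hormone, GRHL motifs lay in 15.5% of the 2438 pan-ER vehicle sites that were Santa Cruz pS118 vehicle sites and in 6.30% of the other 19893, an odds ratio of 2.73. Other motifs differed too, with odds ratios of 1.99 for the full ERE, 1.26 for its single arm, 1.38 for AP-2, 0.692 for FOXA and 0.606 for GATA, and a CTCF motif in 0 of the 2438. For GRHL the odds ratio was 3.18 (interval 2.76 to 3.67) within 50 strata of peak rank. It was 2.69 (2.36 to 3.07) over sites more than 1 kb from a TSS within GC deciles. These values argue against peak strength and against promoters with GC content as the whole cause. Without Cell Signaling vehicle sites it was 2.52 (2.20 to 2.90), so sites called with that antibody are not the whole source. Shared background too weak to be called there is not excluded. Of the 918 Cell Signaling vehicle sites at pan-ER sites, 13.2% carried a GRHL motif as well, against 5.33% of the 75 Abcam ones. The Santa Cruz odds ratio was 1.79 and 1.86 without Santa Cruz vehicle replicate 1 or 3, when 769 and 754 sites remained. What lies behind it stays open, since no biological explanation was tested.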
